A study of Homo sapiens with 12 samples.

How the data were processed

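RNA was sequenced from the cancer tissue of a perfused culture plate, in which breast cancer cells of the MDA-MB-231 line carrying a green fluorescent protein were embedded in fibrin gel. Per the labels, the cancer tissue was grown alone (monoculture), beside hepatic tissue made of HepG2 cells with 2% lung fibroblasts (hepatic co-culture), or beside cardiac tissue made of cardiomyocytes derived from induced pluripotent stem cells with 2% cardiac fibroblasts (cardiac co-culture). Each condition had 4 libraries, which the labels call biological replicates without saying which cultures or seedings they came from, so p-values measure the spread between these libraries. RNA was taken 5 days after the cancer cells were seeded, per the series' design text, and mRNA was selected by its poly(A) tail, per the labels' protocols.

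The values are raw counts of reads per Ensembl gene deposited by the authors, not normalized, in 1 table of 58735 genes and 12 libraries. Per the submitters' processing notes, the tools were HISAT2 2.2.1, featureCounts 2.0.6 and DESeq2 1.42.0, and the genome build was GRCh38; these notes give no order or settings. The annotation release, the read filters and the strand setting of the counting are not given in the sources used here. The labels' protocols describe a library kit that keeps the strand and a kit that does not, without saying which was used, so reads of overlapping and antisense genes cannot be told apart. Treatment of reads that match several places is also not given, so counts of close paralogs (cystatins, keratin 6 genes, metallothioneins, HLA genes, ribosomal proteins with their pseudogenes) are uncertain. Of the deposited gene identifiers, 58735 were found in GENCODE release 29, whose symbols, gene types and GRCh38 coordinates are used; it gives CTGF for CCN2 and CYR61 for CCN1.

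Total counts ranged from 35.0 to 42.0 M (M for 1e6) in the monoculture libraries, from 26.2 to 42.4 M in the hepatic co-culture and from 27.0 to 37.4 M in the cardiac co-culture. After the low-count filter of edgeR (filterByExpr), 17468 genes were tested, which held 99.9% of all counts. The common biological coefficient of variation was 14.9%. The fit was tested on simulated data. On counts with 200 changed genes of known size, run over the same 17468 genes, the fit recovered 41.8% of 1.5-fold, 65.7% of 2-fold and 92.4% of 4-fold changes for hepatic co-culture against monoculture. For cardiac co-culture against monoculture it recovered 59.7%, 77.6% and 93.9%, and for cardiac against hepatic co-culture 58.2%, 76.1% and 95.5%. Each comparison had its own draw of 66 or 67 genes per size, so differences between the comparisons also reflect which genes were drawn. All groups had the same dispersions and no library was made to stand apart, so the spread of the real cardiac libraries is not covered. Between 4.58% and 5.75% of the simulated calls were false, and 0 of 39 unchanged gene lists were called in each simulated comparison. Genes were drawn independently of each other there, so the simulation does not show how the list test behaves where genes vary together.

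Genes were tested with edgeR 4.0.16 (R 4.3.3) by its robust quasi-likelihood test after TMM scaling, in 1 fit over the 12 libraries with group as the factor, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as TMM-scaled counts per 1e6 counts (CPM) with their SD over 4 libraries. The 40 gene lists (pathways, cell cycle phases, cell type markers and RNA quality, 718 genes, 718 of them in the table) were tested with camera of limma 3.58.1 on logCPM (prior count 2) with a preset correlation between genes of 0.01, against all other tested genes. The members of a list were also adjusted over the list alone. Summed CPM of the 6 cell type marker lists was compared by two-sided exact permutation tests, for which 0.0286 is the smallest p with 4 libraries against 4. The resemblance of the co-culture effects, which share the monoculture libraries, was set against simulated unchanged groups and against splits of the monoculture libraries.

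Genes named in the text follow a rule. It takes the 8 highest and 8 lowest log2 fold changes among protein-coding genes past the threshold with mean logCPM above 1 and no overlap between the groups' libraries, of which the first 5 of each are written out. Next came 18 genes chosen for the study's question whatever they did, then the members with the smallest adjusted p of each list called. The rule allowed about 30 genes per comparison, and at most 36 were taken. The rule, the lists, the tests and the alternatives were fixed before the data were examined, except where stated. Alternatives were DESeq2 1.42.0, its size factors in edgeR, upper-quartile scaling, no low-count filter, a replicate block, a minimum log2 fold change of 1, an estimated correlation and fry for the lists, and each library left out in turn. A block by the number in the library names, fits of the compared groups alone, thinning to equal depth, a correction for GC content and transcript length, and leaving out a pair of libraries were added after the data had been seen. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 8.62 to 56.1, r of logCPM 0.977 to 0.985), so none was counted as a duplicate. Plots were drawn with matplotlib 3.10.9.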

Results

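The experiment measured how gene expression in breast cancer tissue differed when hepatic or cardiac tissue was cultured in the same perfused device. MDA-MB-231 is a triple-negative, mesenchymal-like human breast cancer line, and HepG2 is a human hepatoblastoma-derived line that keeps hepatocyte functions. Cancer tissue was sequenced from 3 conditions with 4 libraries each: monoculture, hepatic co-culture and cardiac co-culture. Library totals lay between 26.2 and 42.4 M counts (M for 1e6). Group means were 37.8 ± 3.28 M in monoculture, 32.1 ± 7.12 M in the hepatic and 31.2 ± 4.82 M in the cardiac co-culture (SD, n = 4). Mitochondrial transcripts took 5.06 ± 0.28%, 5.31 ± 0.48% and 4.98 ± 0.40% of the counts in these groups.

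On the first principal component, with 28.5% of the variance, the monoculture libraries lay between -51.1 and -22.3, the hepatic ones between 24.5 and 46.8, and cardiac replicates 1 to 3 between 6.79 and 16.3. Cardiac replicate 4 lay at -24.9, among the monoculture libraries and next to monoculture replicate 2 at -22.3.

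**Figure D1:**
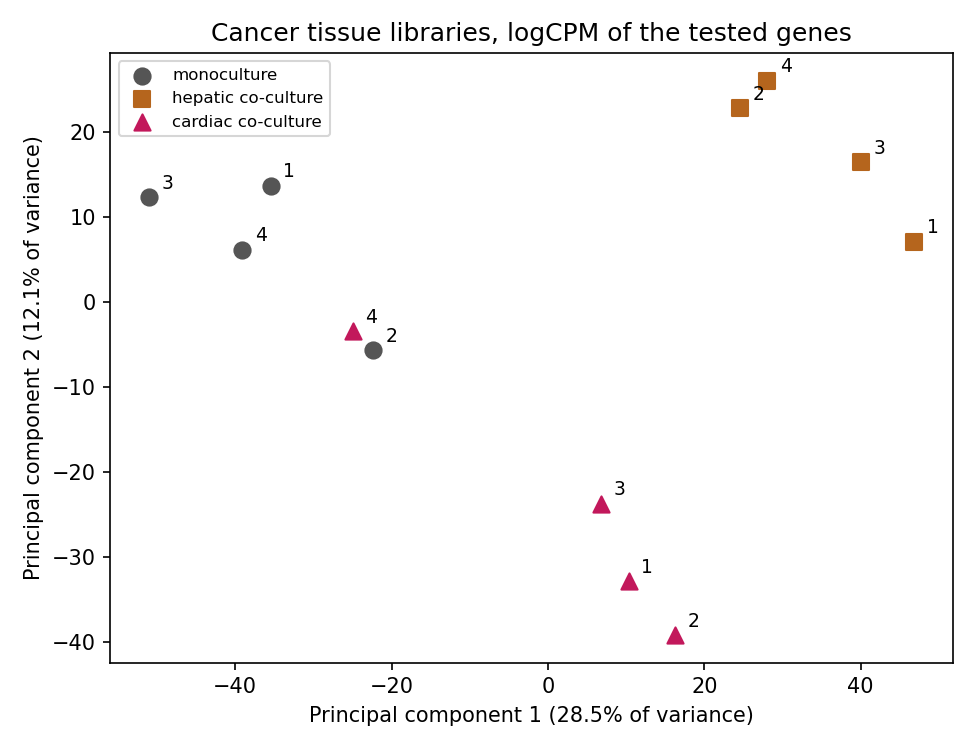
Principal components 1 (28.5% of the variance) and 2 (12.1%) of logCPM over the tested genes, 1 point per library, numbered by replicate, with shape and colour for the 3 conditions. The 4 hepatic libraries stand at the right, cardiac replicates 1 to 3 at the bottom, and cardiac replicate 4 at -24.9 on component 1 beside monoculture replicate 2.

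The cancer tissue was first examined for RNA of the neighbouring tissues. ALB, the main plasma protein of hepatocytes, had 0 to 6 counts in the hepatic libraries and 0 to 14 in monoculture, and APOA1, an apolipoprotein of hepatocytes, had 1 to 4 and 0 to 4. MYH6, a cardiac myosin heavy chain, had 21 counts in cardiac replicate 4 and 0 in the other libraries, and MYL7, an atrial myosin light chain named after its counts were seen, had 8 and 0. Summed hepatocyte markers were 60.2 ± 14.2 CPM in the hepatic co-culture and 86.0 ± 18.2 CPM in monoculture (n = 4, exact permutation p = 0.0857, adjusted p = 0.119). Summed cardiomyocyte markers were 24.8 ± 0.88 CPM in the cardiac co-culture and 20.4 ± 1.54 CPM in monoculture, and summed fibroblast markers 412 ± 59.8 and 285 ± 28.5 CPM (n = 4, each with exact permutation p = 0.0286, adjusted p = 0.0571). COL5A1, a collagen gene named after its values were seen, gave most of the rise in the fibroblast sum (116 CPM in monoculture and 228 in the cardiac co-culture). The fibroblast sum was 296 ± 87.3 CPM in the hepatic co-culture (n = 4, exact permutation p = 0.914 against monoculture). The cardiomyocyte sum was 24.5 ± 0.78 CPM there, with exact permutation p = 0.629 (n = 4) between the co-cultures, so it was not particular to cardiac tissue. TTN, a giant sarcomere protein named after its values were seen, made up most of it (14.7 CPM in monoculture, 19.2 in the hepatic and 17.4 in the cardiac co-culture). Of 18 sums compared, 9 separated the groups completely, at the smallest exact permutation p that 4 against 4 libraries allow. Of a partner tissue's own markers against monoculture, only the cardiomyocyte and fibroblast sums of the cardiac co-culture were among these 9. The others included sums of endothelial markers and of the cancer line's own markers. The adjusted p of these 9 sums, 0.0571 (exact permutation), was limited by the number of libraries, so RNA of other cells is not excluded by these tests. Of the genes in these lists, 2 of 21 hepatocyte, 4 of 23 cardiomyocyte and 9 of 18 fibroblast markers reached 1 CPM in monoculture, so the cancer cells themselves contribute to the sums. TNNT2, a cardiac troponin, and MMP9, a gelatinase, were too low to be tested, as were ALB, APOA1 and MYH6.

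Hepatic co-culture against monoculture asked what nearby hepatic tissue did to the cancer cells. Among the fixed lists, 34 of 39 ribosomal, 18 of 29 matrix and 12 of 18 glycolysis genes rose, and 3 of 6 metallothionein and zinc export and 7 of 20 G1/S genes fell. None of the list calls held with an estimated correlation. LAMA3 and LAMB1, laminin chains of the basement membrane, rose by 1.17 ± 0.10 and 0.78 ± 0.08 on the log2 scale, and LAMA3 went from 62.5 ± 6.83 to 140.4 ± 19.7 CPM (n = 4 each). MT1E, a zinc-binding metallothionein, fell by 1.49 ± 0.07 from 102 ± 6.88 to 36.6 ± 1.99 CPM, and ANGPTL4, an inhibitor of lipoprotein lipase, fell by 2.21 ± 0.18. In all, 4892 of 17468 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2518 higher and 2374 lower, of which 799 changed at least 2-fold.

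Among protein-coding genes with mean logCPM above 1 and no overlap between the groups' libraries, the highest fold changes were those of BMP5, a bone morphogenetic protein (3.83 ± 0.66), FCGR2A, an IgG receptor (3.33 ± 0.73), the secreted cysteine protease inhibitors CST1 (3.23 ± 0.39) and CST4 (3.08 ± 0.29), and ENPP3, an ectonucleotide pyrophosphatase (2.98 ± 0.32). Their adjusted p by edgeR's quasi-likelihood test ran from 4.12e-05 (CST4) to 0.00645 (FCGR2A). CST1 (ENSG00000170373, chromosome 20, 23747553 to 23751268, GRCh38) and CST4 (ENSG00000101441, chromosome 20, 23685640 to 23689040) are close paralogs whose reads may have been split in counting. The lowest within the same limits were ROS1, a receptor tyrosine kinase (-3.27 ± 0.37), the keratin KRT6A (-3.23 ± 0.39), the transcription factor ATOH8 (-3.18 ± 0.25), PGC, a pepsinogen (-3.00 ± 0.37), and CSF3, the granulocyte colony-stimulating factor (-2.91 ± 0.32), with adjusted p from 6.78e-06 (CSF3) to 2.97e-05 (PGC). ATOH8 went from 48.2 ± 16.7 to 5.32 ± 0.39 CPM, while BMP5, FCGR2A, ROS1, KRT6A, PGC and CSF3 had group means under 6 CPM in both groups.

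By gene group, 11 of 40 lists were called by camera, 7 upward and 4 downward. Of 29 genes of extracellular matrix and crosslinking, 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 9.62e-07, adjusted p = 0.721 with an estimated correlation). Of 19 matrix proteolysis genes, 11 rose and 1 fell (also 11 and 1 adjusted over the list alone; camera adjusted p = 0.00177, adjusted p = 0.721 with an estimated correlation). Cytosolic ribosomal proteins rose in 34 of 39 genes (36 adjusted over the list alone), among them RPS4X (0.54 ± 0.08) and RPS3 (0.40 ± 0.07), with camera adjusted p = 2.82e-11 and adjusted p = 0.732 with an estimated correlation. Glycolysis genes rose in 12 of 18 (14 higher and 1 lower adjusted over the list alone), such as GPI (0.51 ± 0.13) and PFKP (0.37 ± 0.10), with camera adjusted p = 4.06e-04 and adjusted p = 0.790 with an estimated correlation. Of 23 hypoxia response genes, 8 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.36e-04, adjusted p = 0.790 with an estimated correlation). VEGFA, the endothelial growth factor, rose by 1.40 ± 0.38 and PFKFB3, an activator of glycolysis, by 1.05 ± 0.27, and the member that fell was ANGPTL4.

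Genes of G1/S fell in 7 of 20 (13 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 5.18e-05, adjusted p = 0.790 with an estimated correlation). They included the cyclin CCNE2 (-0.84 ± 0.24) and CDC6, which loads the replicative helicase (-0.86 ± 0.24). None of 22 G2/M genes passed edgeR's test (0 adjusted over the list alone, 3 lower by unadjusted p), although the list had a median of -0.39 and camera adjusted p = 0.00459 (adjusted p = 0.790 with an estimated correlation). Metallothioneins and zinc export fell in 3 of 6 (5 adjusted over the list alone; median -0.94, camera adjusted p = 5.64e-04, adjusted p = 0.324 with an estimated correlation). Lipid storage and fatty acid oxidation fell in 7 and rose in 2 of 19 genes (7 and 2 adjusted over the list alone; camera adjusted p = 0.0285, adjusted p = 0.732 with an estimated correlation). Long noncoding and intron-rich transcripts of the nucleus, a sign of RNA composition, rose in 7 of 10 (7 adjusted over the list alone), including CCNL1 (0.49 ± 0.09), with camera adjusted p = 0.00333 and adjusted p = 0.732 with an estimated correlation. Endothelial markers rose in 5 and fell in 1 of 8 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00800, adjusted p = 0.534 with an estimated correlation). TIE1, an endothelial receptor tyrosine kinase, rose by 3.10 ± 0.38 to 3.15 ± 0.69 CPM, although the labels name no endothelial cells.

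Among the genes chosen for the study's question, VIM, the mesenchymal intermediate filament, rose by 0.59 ± 0.13, COL3A1, a fibrillar collagen, by 2.84 ± 0.91 to only 0.63 ± 0.28 CPM, and CXCR4, a chemokine receptor linked to metastasis, fell by 1.34 ± 0.43 (edgeR's quasi-likelihood test, adjusted p = 0.00306, 0.0257 and 0.0272). COL1A1 (0.52), MKI67 (-0.66), MMP1 (1.25), CXCL8 (0.73), IL6 (0.33), CD44 (-0.04), CTGF (0.09) and HMOX1 (0.10) did not pass, with adjusted p from 0.0503 for COL1A1 to 0.651 for HMOX1. Without cardiac replicate 4, a library of neither group, COL1A1 (0.52, adjusted p = 0.0457), MKI67 (-0.67, adjusted p = 0.025) and CXCL8 (0.72, adjusted p = 0.0114) passed edgeR's quasi-likelihood test. Of the 28 named genes called here, 23 passed in each of 12 fits that left out 1 library. COL3A1, VEGFA, CXCR4, CCNE2 and CDC6 did not, with adjusted p up to 0.0836 (CXCR4, -1.20 without monoculture replicate 3), and the libraries whose absence ended a call were monoculture replicates 1 to 4 and hepatic replicates 1 to 4.

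Cardiac co-culture against monoculture asked the same of nearby cardiac tissue, for which the study's title names resistance to metastasis. Among the fixed lists, 9 of 18 glycolysis, 12 of 29 matrix, 9 of 21 NF-kB and 5 of 23 hypoxia genes rose, and 4 of 13 heat shock and 6 of 20 YAP/TAZ genes fell, so most members did not pass except for glycolysis. None of the list calls held with an estimated correlation. GPI, a glycolytic isomerase, rose by 0.64 ± 0.13 from 405 ± 82.4 to 631 ± 82.4 CPM. LAMA3 rose by 0.73 ± 0.10, and TNFAIP2, a gene induced by tumour necrosis factor, by 0.66 ± 0.09 from 129.5 ± 5.99 to 205 ± 17.99 CPM (n = 4 each). HSPH1, a chaperone of the HSP110 family, fell by 0.54 ± 0.07 from 259 ± 32.5 to 179 ± 4.89 CPM. In all, 1443 of 17468 genes (8.26%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 862 higher and 581 lower, of which 149 changed at least 2-fold. The share of higher calls was 59.7%, and 72.2% with upper-quartile scaling.

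Within the same limits, the highest fold changes were those of DHRS3, a retinaldehyde reductase (2.16 ± 0.26), CHI3L2, a chitinase-like protein (2.04 ± 0.49), FGG, the fibrinogen gamma chain (2.01 ± 0.53), TGFBI, a matrix protein induced by TGF-beta (1.91 ± 0.40), and SSPO, which encodes SCO-spondin (1.66 ± 0.33). The lowest were BCAS1 (-2.01 ± 0.45), ANKRD1 (-1.26 ± 0.24), PRRG4 (-1.16 ± 0.28), ILDR2 (-1.09 ± 0.26) and ATOH8 (from 48.2 ± 16.7 to 23.98 ± 5.87 CPM). Their adjusted p by edgeR's quasi-likelihood test ran from 7.01e-04 (DHRS3) to 0.0391 (FGG). DHRS3 (ENSG00000162496, chromosome 1, 12567910 to 12617731, GRCh38) had 1.00 ± 0.20 CPM in monoculture and 4.50 ± 1.58 in the cardiac co-culture, and TGFBI (ENSG00000120708, chromosome 5, 136028895 to 136063818) 32.9 ± 12.5 and 124 ± 49.6 CPM. VEGFA rose by 1.56 ± 0.38, while MMP1 (2.01 ± 0.66, adjusted p = 0.0910), CXCL8 (1.34 ± 0.36, adjusted p = 0.0535), IL6 (0.50), VIM (0.34), COL1A1 (0.03), COL3A1 (1.95), MKI67 (-0.35), CD44 (-0.17), HMOX1 (0.04) and CXCR4 (-0.41) did not pass edgeR's quasi-likelihood test.

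Camera called 21 of 40 lists, 14 upward and 7 downward. Hypoxia response genes had the highest median of the lists called (1.00), and 5 of 23 rose (22 adjusted over the list alone; camera adjusted p = 7.67e-12, adjusted p = 0.386 with an estimated correlation). Glycolysis genes rose in 9 of 18 (16 adjusted over the list alone; median 0.66, camera adjusted p = 2.05e-09, adjusted p = 0.386 with an estimated correlation). Of 29 matrix and crosslinking genes, 12 rose and 2 fell (22 and 2 adjusted over the list alone), among them P4HA2, a collagen prolyl hydroxylase (0.50 ± 0.11), with camera adjusted p = 7.73e-09 and adjusted p = 0.386 with an estimated correlation. NF-kB cytokines and inflammation rose in 9 of 21 (15 adjusted over the list alone), including TNFAIP2, with camera adjusted p = 8.10e-07 and adjusted p = 0.386 with an estimated correlation. Matrix proteolysis genes rose in 5 of 19 (9 adjusted over the list alone), including PLAUR, the urokinase receptor (0.44 ± 0.08), with camera adjusted p = 0.00152 and adjusted p = 0.386 with an estimated correlation. The unfolded protein response of the endoplasmic reticulum rose in 5 of 16 (7 adjusted over the list alone), led by its chaperone HSPA5 (0.41 ± 0.08, to 1387 ± 133 CPM; camera adjusted p = 1.17e-04, adjusted p = 0.386 with an estimated correlation). Ribosomal proteins rose in 6 of 39 (14 adjusted over the list alone), such as RPS27 (0.41 ± 0.10), with camera adjusted p = 3.26e-07 and adjusted p = 0.437 with an estimated correlation.

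In the lists called downward, heat shock proteins fell in 4 of 13 (4 adjusted over the list alone; camera adjusted p = 0.00152, adjusted p = 0.386 with an estimated correlation). YAP/TAZ targets fell in 6 and rose in 1 of 20 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00427, adjusted p = 0.386 with an estimated correlation). The YAP/TAZ targets CYR61 and CTGF, both secreted matricellular proteins, fell by 0.58 ± 0.11 and 0.38 ± 0.10, beside ANKRD1. Nuclear genes of oxidative phosphorylation fell in 4 of 30 (6 adjusted over the list alone), such as NDUFA4 (-0.28 ± 0.07), with camera adjusted p = 9.07e-05 and adjusted p = 0.403 with an estimated correlation. NRF2 targets fell in 3 and rose in 1 of 21 (6 and 1 adjusted over the list alone), including GCLM, a subunit of the enzyme that starts glutathione synthesis (-0.47 ± 0.09), with camera adjusted p = 0.01 and adjusted p = 0.386 with an estimated correlation. No gene of G1/S (20) or G2/M (22) passed edgeR's test (0 adjusted over either list alone, 11 and 2 lower by unadjusted p). The medians were -0.46 and -0.38, with camera adjusted p = 4.02e-07 and 5.21e-06 (adjusted p = 0.403 and 0.449 with an estimated correlation). Immediate early genes rose in 4 and fell in 1 of 21 (7 and 1 adjusted over the list alone), including the transcription factor EGR1 (0.50 ± 0.12), with camera adjusted p = 0.00900 and adjusted p = 0.403 with an estimated correlation. Intron-rich nuclear transcripts rose in 2 of 10 (3 adjusted over the list alone), 1 of them CCNL2 (0.34 ± 0.10), with camera adjusted p = 0.00195 and adjusted p = 0.386 with an estimated correlation. Genes of epithelial-mesenchymal transition rose in 3 of 10 (6 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0249 and adjusted p = 0.402 with an estimated correlation.

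The other 5 calls in this comparison each ended without at least 1 library. They were antigen presentation (4 of 16 rose), the ATF4 amino acid response (4 of 19 rose), a breast cancer lung metastasis signature (1 of 12 rose), endothelial markers (3 of 8 rose) and cholesterol biosynthesis (1 of 22 fell). Adjusted over the list alone, 5, 5, 5, 3 and 1 of their genes rose and 0, 1, 1, 0 and 1 fell. Their camera adjusted p were 0.0372, 0.0232, 0.0412, 0.0412 and 0.0399 (adjusted p = 0.453, 0.462, 0.386, 0.386 and 0.528 with an estimated correlation). The largest adjusted p after an omission was 0.388, for antigen presentation without cardiac replicate 4. The call also ended for antigen presentation without monoculture replicate 1 or 2, for the ATF4 response without monoculture replicate 1 or cardiac replicate 1 or 2, and for cholesterol biosynthesis without monoculture replicate 3 or cardiac replicate 4. For the lung metastasis signature these were monoculture replicates 2, 3 and 4 and cardiac replicates 1 and 3, and for endothelial markers monoculture replicates 1 and 2, hepatic replicate 2 and cardiac replicate 3.

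This comparison rested on single libraries more than the others. The count of 1443 genes became 558, 369 and 518 without monoculture replicates 1, 3 and 4, and 523, 263 and 397 without cardiac replicates 1, 2 and 3. It became 3378 without cardiac replicate 4, with 1420 of the 1443 genes still called, and 3448 when monoculture replicate 2 was left out as well. Of 25 named genes called, 10 passed in each omission (DHRS3, SSPO, GPI, LAMA3, TNFAIP2, HSPA5, HSPH1, PLAUR, CYR61 and GCLM). The other 15 lost their call without at least 1 library, among them VEGFA (1.33 without cardiac replicate 2, adjusted p = 0.122 by edgeR's quasi-likelihood test), FGG (1.84, adjusted p = 0.114) and CCNL2 (0.24, adjusted p = 0.171), both also without cardiac replicate 2. When cardiac replicate 4 was left out, 6 of the genes chosen for the study's question passed that had not passed with it. By edgeR's quasi-likelihood test these were MMP1 (2.37, adjusted p = 0.0107), CXCL8 (1.62, adjusted p = 5.16e-04) and IL6 (0.70, adjusted p = 0.00220). The same test gave VIM (0.45, adjusted p = 0.00541), CD44 (-0.20, adjusted p = 0.0349) and MKI67 (-0.69, adjusted p = 0.0480).

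**Figure D2:**
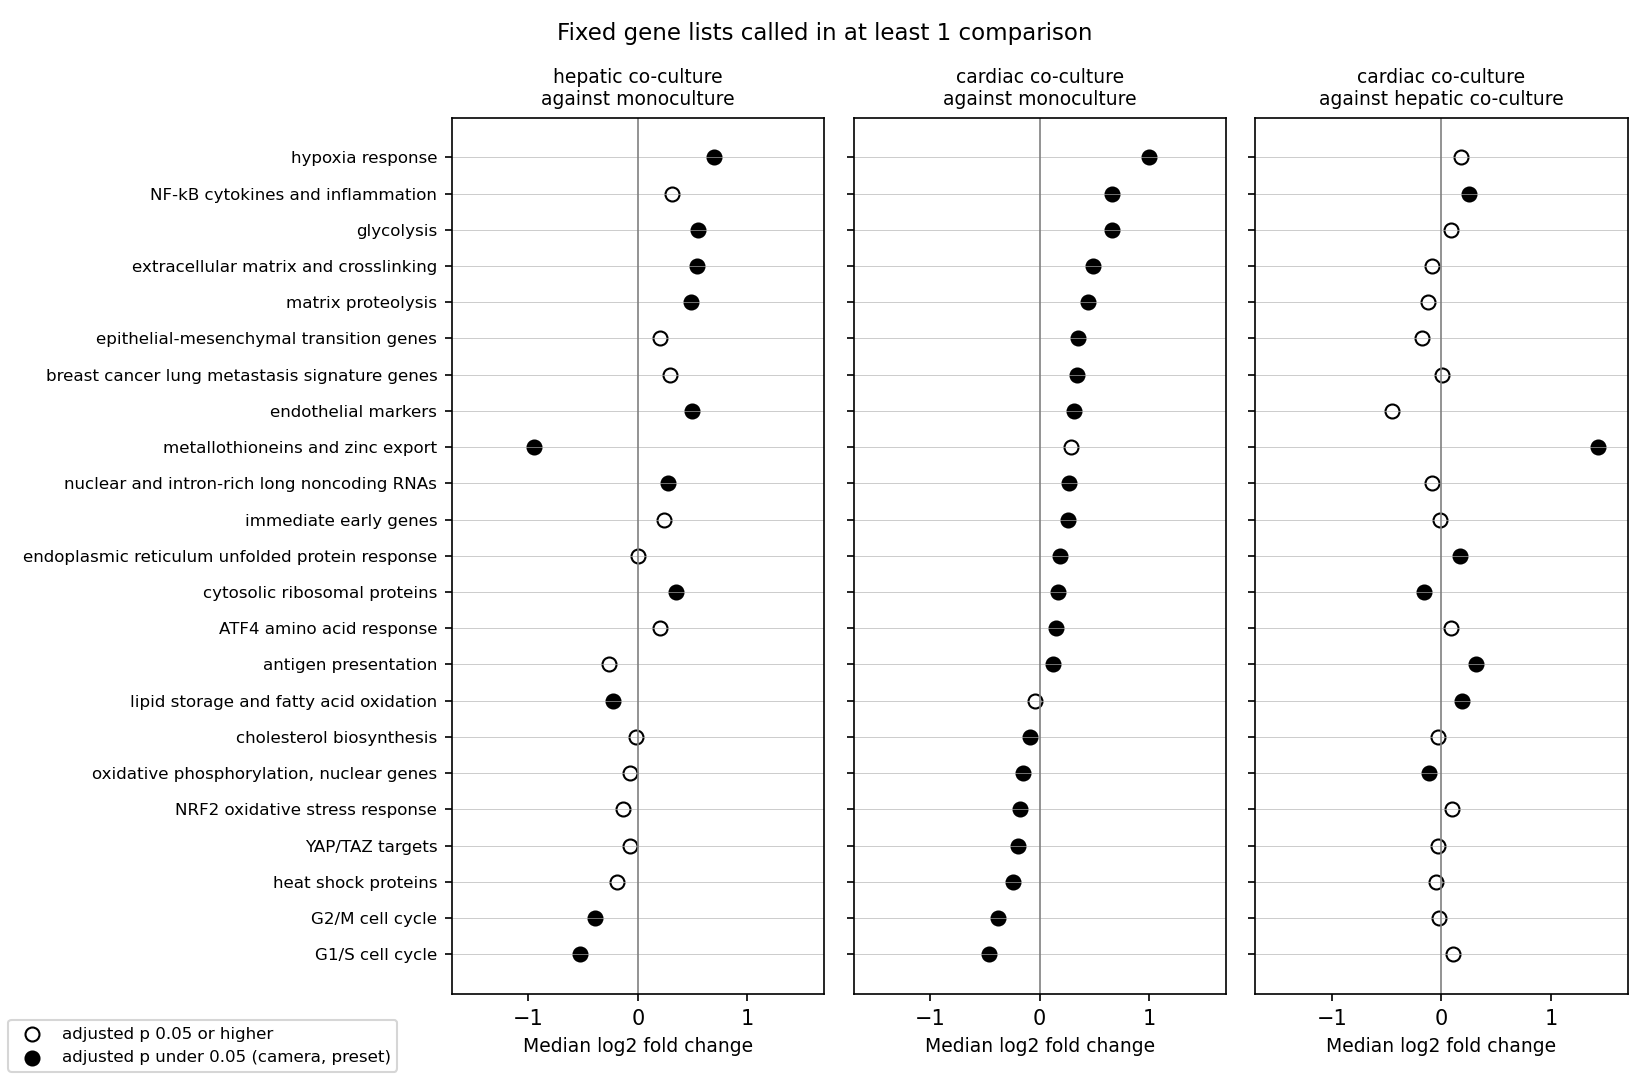
Median log2 fold change of the members of each gene list called in at least 1 comparison, in 3 panels for the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. Hypoxia response stands at 0.70 and 1.00 in the co-cultures against monoculture, and metallothioneins at -0.94 in the hepatic co-culture and 1.43 in cardiac against hepatic.

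Cardiac against hepatic co-culture compared the neighbours directly. Beside cardiac tissue 3 of 6 metallothionein and zinc export, 6 of 16 antigen presentation and 4 of 19 lipid genes were higher, and none of these list calls held with an estimated correlation. The cystatin genes CST1, CST2 and CST4 were higher beside hepatic tissue. MT1E was higher by 1.80 ± 0.07 (127 ± 7.53 against 36.6 ± 1.99 CPM), MT2A by 1.07 ± 0.08 and ANGPTL4 by 2.39 ± 0.18 (181 ± 24.5 against 34.4 ± 8.49 CPM), all in 4 against 4 libraries. CTGF was lower by 0.46 ± 0.10 on the log2 scale (-0.46). In all, 1080 of 17468 genes (6.18%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 572 higher and 508 lower in the cardiac co-culture, of which 198 changed at least 2-fold.

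Within the same limits, the highest were CSF3 (3.09 ± 0.33), the formin DAAM2 (3.03 ± 0.32), KRT6A (2.96 ± 0.39), the inositol hexakisphosphate kinase IP6K3 (2.64 ± 0.32) and ANKRD35 (2.63 ± 0.17). The lowest were HHIP, a binder of hedgehog ligands (-2.75 ± 0.45), CST1 (-2.72 ± 0.39), CST4 (-2.48 ± 0.28), ENPP3 (-2.32 ± 0.31) and CST2 (-2.13 ± 0.29). Adjusted p by edgeR's quasi-likelihood test ran from 2.44e-08 (ANKRD35) to 0.00272 (HHIP). In monoculture CSF3, KRT6A and ANKRD35 had 2.85 ± 0.93, 3.93 ± 0.83 and 8.41 ± 0.77 CPM, against 0.39 ± 0.16, 0.44 ± 0.26 and 1.17 ± 0.16 in the hepatic and 3.22 ± 0.36, 3.24 ± 1.32 and 7.22 ± 0.87 in the cardiac co-culture.

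Of 40 lists, 7 were called, 5 upward and 2 downward. Antigen presentation was higher in 6 of 16 genes (8 adjusted over the list alone), led by HLA-DRA (1.40 ± 0.12), HLA-DRB1 (1.51 ± 0.20) and CIITA, the master regulator of class II genes (1.65 ± 0.17), with camera adjusted p = 4.37e-06 and adjusted p = 0.637 with an estimated correlation. Metallothioneins and zinc export were higher in 3 of 6 (4 adjusted over the list alone), with MT1X at 1.83 ± 0.35 (camera adjusted p = 5.47e-06, adjusted p = 0.0682 with an estimated correlation). NF-kB genes were higher in 4 of 21 (5 adjusted over the list alone), including the apoptosis inhibitor BIRC3 (1.46 ± 0.13) and NFKBIA, the inhibitor of NF-kB (0.69 ± 0.16), with camera adjusted p = 1.14e-04 and adjusted p = 0.874 with an estimated correlation. The unfolded protein response was higher in 5 of 16 (7 adjusted over the list alone), such as the chaperones HYOU1 (0.38 ± 0.06), HSPA5 (0.39 ± 0.08) and DNAJC3 (0.26 ± 0.06), with camera adjusted p = 7.94e-04 and adjusted p = 0.637 with an estimated correlation. Lipid storage and fatty acid oxidation was higher in 4 of 19 (7 adjusted over the list alone), with ACSL1, an acyl-CoA synthetase, at 0.86 ± 0.14 (camera adjusted p = 0.0119, adjusted p = 0.637 with an estimated correlation). Ribosomal proteins (median -0.16) and oxidative phosphorylation (median -0.11) were called downward with 0 of 39 and 0 of 30 genes past edgeR's test (0 adjusted over either list alone, 13 and 4 lower by unadjusted p; camera adjusted p = 5.47e-06 and 0.0489, adjusted p = 0.874 and 0.874 with an estimated correlation). None of the 11, 21 and 7 camera calls of the 3 comparisons held with an estimated correlation. Camera with that correlation had 2, 2 and 2 lists by unadjusted p, and fry called 13, 17 and 5.

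COL1A1, COL3A1, VIM, CD44, MKI67, MMP1, IL6, CXCL8, VEGFA (0.16 ± 0.37), HMOX1 and CXCR4 did not pass edgeR's test between the co-cultures. CXCL8 passed edgeR's quasi-likelihood test without cardiac replicate 4 (0.90, adjusted p = 0.0219). The count of 1080 became 676 without hepatic replicate 3, and 7 called lists became 12 without cardiac replicate 4. NFKBIA lost its call without hepatic replicate 1, 2 or 3 or cardiac replicate 1, 2 or 3 (adjusted p up to 0.0809 by edgeR's quasi-likelihood test, without hepatic replicate 3). CTGF lost it without cardiac replicate 3 (-0.44, adjusted p = 0.0544 by the same edgeR test with Benjamini-Hochberg adjustment). The call of oxidative phosphorylation ended without 9 of the 12 libraries in turn, monoculture 1 to 4, hepatic 1, 2 and 4 and cardiac 2 and 3 (camera adjusted p up to 0.343, without cardiac replicate 2).

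**Figure D3:**
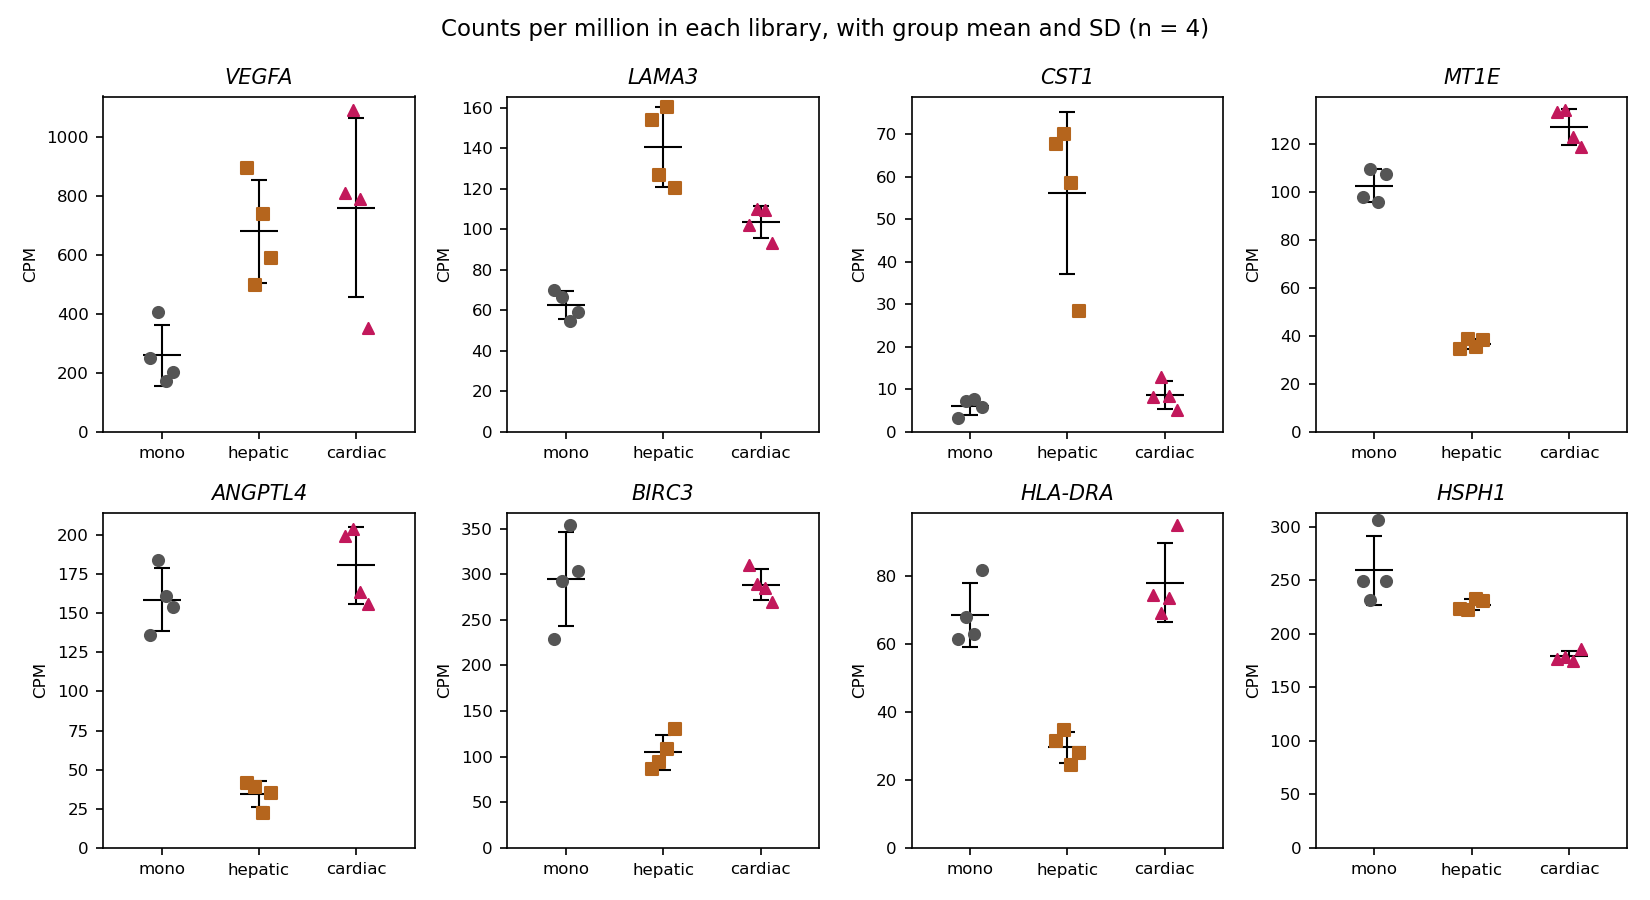
CPM of 8 genes in each of the 12 libraries (points), with the mean and SD of 4 libraries per condition (horizontal line and bar), on linear axes from 0. MT1E, ANGPTL4, BIRC3 and HLA-DRA are lowest in the hepatic co-culture, CST1 is highest there, and VEGFA is higher in both co-cultures than in monoculture, with cardiac replicate 4 below the other cardiac libraries.

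The effects of the neighbours on the cancer tissue resembled each other across genes, which are not independent replicates. Pearson's r between the log2 changes against monoculture was 0.660 and Spearman's rho 0.670 over 17468 genes, where simulated unchanged groups against the same monoculture libraries gave r = 0.485. The covariance was 0.152, against a simulated 0.0387, a difference of 0.113, and with the monoculture libraries split between the comparisons it was 0.113 and r was 0.419 (mean of 6 splits, 0.380 to 0.451). The split comparisons share no library, so the simulated r of 0.485 is not the value to set 0.419 against. Of the 1443 genes called in the cardiac co-culture, 677 were called higher and 404 lower in both co-cultures, and 13 were called in opposite directions. Independent lists of the same sizes would share 124 genes higher and 79.0 lower. That expectation leaves out the shared monoculture libraries, from which part of the overlap comes, and no value for unchanged groups was computed for the overlap.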

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

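The swap of labels was tested, and the conditions that leave it and a mislabelled library open were chosen, after the values that decide them had been seen. The other tests were written down before their results were seen, although the patterns themselves came from these data.

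In 20 of 309 groups of 4 libraries (6.47%, where chance gives about 5%) 1 library stood far from the others. Cardiac replicate 4 stood low in the mean logCPM of matrix proteolysis genes (5.25) and in MMP1 (21.4 CPM), and high in antigen presentation (6.64) and ATOH8 (32.8 CPM). Monoculture replicate 3 stood apart in matrix proteolysis (5.003), CXCL8 (22.0 CPM) and CDC6 (55.4 CPM), and monoculture replicate 2 in P4HA2 (80.02 CPM) and in the share of the 10 most counted genes (6.94%). Monoculture replicate 1 stood apart in PGC (2.38 CPM) and monoculture replicate 4 in COL3A1 (0.333 CPM). Hepatic replicate 1 stood apart in cytosolic ribosomal proteins (9.63), P4HA2 (94.1 CPM) and summed cardiomyocyte markers (23.4 CPM), hepatic replicate 3 in ATOH8 (5.89 CPM) and CCNE2 (2.47 CPM), and hepatic replicate 4 in immediate early genes (4.30) and HLA-DRB1 (1.49 CPM). Cardiac replicate 1 stood apart in HYOU1 (249 CPM) and cardiac replicate 2 in summed fibroblast markers (501 CPM).

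The effects of hepatic and of cardiac tissue differed by a test of the difference itself in 1080 genes. The difference was also called by camera for 7 lists, with medians (cardiac minus hepatic) of 1.43 for metallothioneins and zinc export, 0.31 for antigen presentation, 0.25 for NF-kB cytokines and inflammation, 0.18 for lipid storage and fatty acid oxidation, 0.17 for the unfolded protein response, -0.11 for oxidative phosphorylation and -0.16 for ribosomal proteins. None of the 7 held with an estimated correlation (adjusted p = 0.0682 for metallothioneins, 0.637 to 0.874 for the others).

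Cardiac replicate 4 lay near the monoculture libraries. Over the 3376 genes called between cardiac replicates 1 to 3 and monoculture it showed 28.5% of the mean change, where cardiac replicates 1 to 3, each held out and measured over the 1574 to 2721 genes of its own fit, showed 70.5% to 103%. Its greater depth is argued against, since the share was 28.6% at equal depth. A monoculture library labelled as cardiac cannot be told apart from a cardiac well with a small response, because 28.5% lies below the highest held-out monoculture library (44.1%, replicate 2) and above the others (-17.2% to 9.85%), and 15 cardiac markers under 0.1 CPM in monoculture, with 77 counts in this library and 3 to 22 in monoculture, had only 23, 7 and 7 in cardiac replicates 1 to 3. A swap with monoculture replicate 2 cannot be told apart either, since over 3441 genes called without both libraries that replicate showed 44.1% and cardiac replicate 4 35.1% of the change, and the swapped labels gave 1639 calls against 1464. The 15 cardiac markers go with the given labels, with 77 counts in cardiac replicate 4 (21 of them MYH6) and 3 in monoculture replicate 2. They rest on 1 library and do not decide it, since cardiac replicates 1 to 3 had 23, 7 and 7.

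Hypoxia and glycolysis lists were called higher, and G1/S and G2/M lists lower, in both co-cultures, and none of these 8 calls held with an estimated correlation (adjusted p = 0.386 to 0.790). Lower depth of the co-culture libraries and GC or length bias are argued against as the whole cause, since 8 of the 8 calls stayed at equal depth and 8 with the GC and length correction. A growth or oxygen state that also varies between wells of 1 condition may contribute, with r = -0.69 between the scores. Within conditions, libraries with higher hypoxia scores had lower G1/S scores (exact permutation p = 0.00702; rho = -0.67, exact permutation p = 0.0201; 12 libraries, 1 relation computed, so adjusted values are the same). The relation rests in part on monoculture replicate 2 and cardiac replicate 4, without which r was -0.57 with exact permutation p = 0.112. An effect of the neighbouring tissue on the same state is the other open explanation and was not separated from it.

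Other splits of the 8 libraries of each comparison into 4 and 4 were fitted. For genes in hepatic co-culture against monoculture, 1 of 35 splits, the labelled one, gave as many calls as the labels (5154, highest other 1). For cardiac against hepatic co-culture it was also 1 of 35 (770, highest other 10). No other split came near the labels there, but 1 of 35 is the smallest share this count can give, so it cannot by itself exclude chance. For cardiac co-culture against monoculture 2 of 35 splits gave as many calls (1464, highest other 1639), so chance cannot be excluded by this count. The other split is that of the swapped labels. For the number of lists called, 4, 5 and 23 of 35 splits gave as many in hepatic against monoculture (13, highest other 16), cardiac against monoculture (18, highest other 20) and cardiac against hepatic (6, highest other 15), so chance cannot be excluded for any of these counts.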

How the results depend on the processing

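The block by library-name number, fits of the compared groups alone, thinning, the GC and length correction, the omission of a pair of libraries, and the alternatives for the marker sums and for single omissions in the correlation of the effects were chosen after the data had been seen. No called gene or list reversed its direction under any alternative run. The share of higher calls in hepatic against monoculture was 51.5%, and between 48.3% with the GC and length correction and 59.9% with upper-quartile scaling. A minimum log2 fold change of 1 left 799, 149 and 198 genes in hepatic against monoculture, cardiac against monoculture and cardiac against hepatic, by construction. With an estimated correlation 0, 0 and 0 lists were called, and with fry 13, 17 and 5; the cause was not tested. In cardiac against monoculture DESeq2 called 2237 genes and the fit with no low-count filter 2219; the cause was not tested. In the other comparisons DESeq2 called 5167 and 1521. Omitting single libraries gave 3660 to 5529, 263 to 3378 and 676 to 1269 genes and 11 to 13, 18 to 23 and 6 to 12 lists. Omitting both monoculture replicate 2 and cardiac replicate 4 gave 5360, 3448 and 872 genes and 13, 23 and 12 lists. The correlation of the effects was 0.419 with split monoculture libraries, 0.765 for genes with mean logCPM above 3, and 0.619 to 0.708 without single libraries. Over all alternatives 717 list values stayed on their side of the threshold and 102 lost it, and 2189 values of named genes stayed, 150 lost it and 37 gained it. No called list changed direction with either other scaling; 18 of 21 cardiac against monoculture calls stayed with upper-quartile scaling. Replicate numbers share only a number: 1 of 12 pairs of the same replicate number had a correlation of deviations over 0.1 (range -0.08 to 0.11), and 3 of 12 libraries correlated best with their own number. With the replicate block by these numbers 4660, 1310 and 891 genes and 11, 18 and 6 lists were called. The numbers in the library names differ from the replicate numbers and pair the cardiac libraries differently, and the labels do not say whether they mark plates, devices or seedings. By those numbers 0 of 8 pairs had a correlation over 0.1 (-0.05 to 0.09), and 2 of 10 libraries with a partner correlated best with their own number. With them as the replicate block edgeR called 4040, 0 and 276 genes (6279, 2032 and 2512 by unadjusted p) and camera 11, 16 and 6 lists. Cardiac replicates 1 and 3 have numbers that no other library has, so this block takes them out of the comparisons. The cardiac effects then rest on cardiac replicates 2 and 4, and replicate 4 lay near monoculture. Whether this is the whole cause of the fewer calls was not tested.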

Other observations

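The lists of glucocorticoid receptor targets and of acute-phase genes were written after the tables of all genes had been seen. They were to leave out the genes noticed there, but the receptor list still holds NFKBIA, PDK4 and GADD45B, which the naming rule had also taken. NFKBIA and PDK4 count among its genes that fell in the hepatic co-culture, and NFKBIA among those higher in cardiac against hepatic. The receptor list is therefore not free of genes already seen. The dilution by hepatic RNA was tested after its deciding values had been seen, on markers that replaced a first choice of hepatocyte markers. FKBP5, SAA2, CFB, C1S, SERPINA1, HP, FGG, AFP, MSN, LGALS1, CAV1 and the receptor targets below were named after their values were seen.

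Genes of the hepatic co-culture that differed from both other conditions in the same direction numbered 474 lower (445 protein-coding) and 389 higher (362 protein-coding). FKBP5, a co-chaperone induced by the glucocorticoid receptor, fell from 300.4 ± 44.2 CPM in monoculture to 45.7 ± 7.02 CPM in the hepatic co-culture, with 245 ± 29.2 CPM in the cardiac co-culture (n = 4 each; -2.71 ± 0.13, edgeR's quasi-likelihood test, adjusted p = 4.71e-09). Of 21 other receptor targets tested, 10 fell and 2 rose against monoculture, among them TSC22D3 (-0.98 ± 0.11), DUSP1 (-1.11 ± 0.12) and MAOA (-1.30 ± 0.10), while SGK1 rose by 0.68 ± 0.20. In cardiac against hepatic co-culture 9 were higher and 0 lower (camera p = 7.84e-10, p = 0.0208 with an estimated correlation).

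RNA of the hepatic tissue diluting that of the cancer tissue would lower the markers of the breast cancer line. Their sum was 610.3 CPM higher than in monoculture (6564 ± 135 against 5954 ± 285 CPM, n = 4). Members went both ways, and VIM (728 to 1098 CPM), MSN (927 to 1116) and LGALS1 (496 to 677) carried the rise, so the sum cannot measure a small dilution. The member that fell most, CAV1, went from 699 ± 38.2 to 513 ± 49.5 CPM. That is far less in proportion than FKBP5, which argues against dilution as the whole cause of the fall of FKBP5. The hepatocyte sum decides little, being mostly SERPINA1 and HP, which monoculture expresses. FGG was higher than in monoculture (5.06 against 0.889 CPM), but also in the cardiac co-culture (3.59 CPM), so its rise was not particular to hepatic tissue. AFP, which was not tested, overlapped between the groups, with 0 to 14 counts in the hepatic libraries and 0 to 11 in monoculture (means of 0.254 and 0.0883 CPM). ALB overlapped too, with 0 to 6 and 0 to 14 counts. AFP and ALB thus showed no hepatic RNA, but such low counts cannot exclude a small amount of it. Lower depth of the hepatic libraries is argued against too, since 92.8% of the 474 genes stayed past the threshold in both comparisons at equal depth. Lower glucocorticoid receptor activity beside hepatic tissue is a possible explanation that the list leaves undecided. Against monoculture 10 of its 21 members fell and 2 rose, with a median of only -0.11 and camera p = 0.00579 (p = 0.241 with an estimated correlation). The labels do not say what the medium held, so a difference in medium or its clearance stays open and untested.

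In the cardiac co-culture, 3 of 16 acute-phase and complement genes tested rose against monoculture (SAA2 by 1.32 ± 0.30, CFB by 1.23 ± 0.18 and C1S by 1.29 ± 0.28) and 0 fell, with a list median of 0.99 (camera p = 1.90e-05, p = 0.0550 with an estimated correlation). CFB rose as much in the hepatic co-culture (1.24 ± 0.18), and neither CFB (-0.02) nor C1S (0.76) passed edgeR's test between the co-cultures, so among these 3 only SAA2 (1.54 ± 0.30) was higher beside cardiac than beside hepatic tissue. In the hepatic co-culture 4 rose and 3 fell (median -0.15, camera p = 0.747), and in cardiac against hepatic 6 were higher and 1 lower (camera p = 3.86e-05, p = 0.0629 with an estimated correlation). The list median of 0.99 is in line with an acute-phase response in the cancer tissue beside cardiac tissue, as a hypothesis; no technical explanation of it was tested, and SAA1 and SAA2 are close paralogs.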
